A study of Ovis aries with 15 samples.

How the data were processed

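RNA of placental cotyledons from Suffolk ewes was sequenced in 15 libraries. The cotyledon is the fetal side of a placentome, the button-like unit in which fetal and maternal tissue of the ruminant placenta interlock. The libraries formed 5 groups of 3, and the labels gave each library an ewe of its own, so replicates were taken as separate animals. Control ewes ate seed of tall fescue free of the fungal endophyte and were sampled near gestation days 85, 110 and 133. E+ ewes ate endophyte-infected seed, which carries ergot alkaloids, and were sampled near days 110 and 133. No E+ group existed at day 85. The day 85 group carried an age label of 86 days and is called day 85 here, after its title. Per the labels, 14 libraries came from Type B placentomes and 1, control day 85 replicate 3, from Type A, types being classes of placentome shape. The start of feeding and the alkaloid dose are not given in the sources used here.

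Per the labels' protocols, total RNA was extracted with Trizol, purified on PureLink columns and made into libraries with an NEBNext Ultra II kit. The submitters' processing notes name bcl2fastq 2.20, FastQC, Trim Galore 0.38, GSNAP, Subread featureCounts 2.0.0 and edgeR 3.22.5, with no settings. The genome build, the annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene for all 15 libraries, not normalized. It held 27054 Ensembl-style sheep gene IDs, of which 1724 had 0 counts in every library, and no line other than genes. Column totals ran from 4030388 to 6159405 counts. Where reads of near-identical gene copies, overlapping genes or antisense partners were divided is unknown, so values of such genes are uncertain.

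The table does not pair its IDs with gene symbols. The only symbol table at hand, for assembly ARS-UI_Ramb_v3.0, lists no Ensembl IDs, and 0 IDs matched. Gene lists for placental hormones, vessels, transport, immune cells and other themes had been fixed before the data were examined, as had the rule that named genes must carry a symbol. Neither could be applied, so no gene list or cell type marker was tested and genes are described as sets. The rule would have named the largest rises and falls past the threshold, with an average log2 CPM (counts per 1000000 counts) of at least 2 and groups that do not overlap. The same rule without the symbol was used to choose 3 IDs, 1 from the E+ comparison at day 110 and 1 rise and 1 fall from the control time course. That change was made after the table was seen.

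Counts were analysed in R 4.3.3. Genes were kept with edgeR 4.0.16 filterByExpr, which left 14653 genes holding 99.72% of all counts. Libraries were scaled by TMM. A quasi-likelihood model (glmQLFit and glmQLFTest, two-sided) with 1 mean per group was fitted to all 15 libraries together, so that all groups shared the estimate of spread, and 8 contrasts were tested. The p-values were adjusted by the Benjamini-Hochberg method within each contrast, at a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Log2 CPM values for principal components and library positions used a prior count of 2. The designs, and every alternative not named below as added later, were fixed before the data were examined.

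The position of a library between control days 85 and 133 was computed with that library left out. Genes with an unadjusted p under 0.001 between control days 85 and 133 were taken, and the library was projected on the line from the day 85 mean, at 0, to the day 133 mean, at 1. Groups were compared by exact two-sided permutation tests, for which 3 animals against 3 allow no p under 0.1. Genes were counted as detected after random thinning of every library to 4030388 counts. Correlations of fold changes run across genes, which are not independent replicates. They were set against other splits of the libraries by absolute r, the real split included. There were 10 splits for 6 libraries, and all 100 pairs of splits within both days were used. For counts of called genes, 100 splits within both days were used, the real one and others drawn at random.

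The tests were tried on simulated counts of 14653 genes, with 200 genes changed in the E+ day 110 libraries in each of 5 runs. Genes were drawn independently, with 1 spread per gene in all groups and no displaced library. edgeR recovered 21.8% of genes changed 2-fold and 82.6% of those changed 4-fold, and 3.87% of its calls were false. limma-voom recovered 19.8% and 78.8% with 2.18% false calls. DESeq2 recovered 37.8% and 86.6% with 13.5% false calls, above the nominal share. In the real data, log2 CPM of E+ day 110 replicate 3 correlated at 0.922 and 0.899 with replicates 1 and 2. Those 2 correlated at 0.970 with each other. The simulated shares may therefore not carry over to the real comparison at day 110. Over the 12265 genes with an average log2 CPM of at least 2, the median 95% interval of a log2 fold change between groups of 3 reached 0.54 to either side. That interval is not adjusted for the number of genes tested, so it is no detection limit. Larger changes could also be missed, as edgeR missed most simulated 2-fold changes.

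The alternatives were DESeq2 1.42.0, limma 3.58.1 voom, DESeq2 size factors, upper-quartile scaling, scaling without the 20 most abundant genes, no filter, a filter of 1 CPM in 3 libraries, only the libraries of a comparison, a replicate block, and leaving out each library. Voom with library quality weights, 1 to 3 surrogate variables (sva 3.50.0) and leaving out 2 displaced libraries were added after the data were seen. Replicates of each group differed far beyond sampling noise, so none was a duplicate. The labels give no batch or date of sequencing.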

Results

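Transcript counts were obtained from placental cotyledons of 15 ewes in 5 groups of 3. Ewes ate tall fescue seed that was endophyte-free (control) or endophyte-infected (E+). Ergot alkaloids made by the endophyte act on serotonin, dopamine and adrenergic receptors and constrict blood vessels. The comparisons ask what E+ feeding changes in late gestation, and how the control cotyledon changes from day 85 to day 133. Total counts averaged 5393000 ± 208200 in control day 85, 5195000 ± 86830 in control day 110 and 4799000 ± 666700 in E+ day 110 libraries (SD, n = 3). They averaged 5509000 ± 563100 in control day 133 and 5344000 ± 352300 in E+ day 133 libraries (SD, n = 3). The lowest total, 4030388, belonged to E+ day 110 replicate 3 and the highest, 6159405, to control day 133 replicate 3.

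The first principal component of log2 CPM held 36.55% of the variance and set most day 133 libraries apart from the rest, and the second held 14.85%. On the first, control libraries of days 85 and 110 lay between -46.7 and -8.74, and 5 of the 6 day 133 libraries between 24.4 and 58.5. 2 libraries stood apart from their day on this component. E+ day 110 replicate 3 lay at 48.0, among the day 133 libraries, and control day 133 replicate 2 at -8.43, near the earlier ones. On the second component, E+ day 110 replicate 3 lay at 42.6, above all day 133 libraries, which lay at -36.0 to 24.9. Control day 133 replicate 2 lay there at -34.8, near control day 133 replicate 1 at -36.0. It was below all libraries of days 85 and 110, the lowest of which lay at -9.09, so it did not stand apart from its day there. The nearest other library belonged to the same group for 3 of the 15 libraries. In E+ day 110 replicate 3 a single gene took 5.46% of all counts (220006 counts), against 0.0198% to 1.48% in the other libraries.

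**Figure D1:**
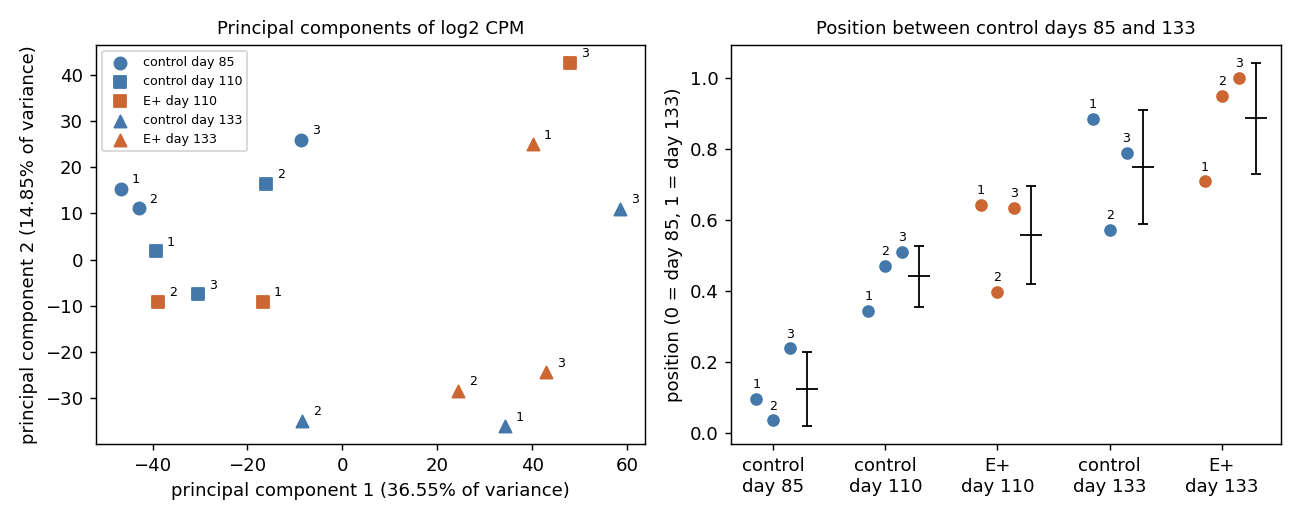
The left panel plots the first principal component (x axis, 36.55% of variance) against the second (y axis, 14.85%) of log2 CPM, 1 point per library, coloured by feed and shaped by day. The right panel plots each library's position between control day 85 (0) and control day 133 (1), with the group mean and SD (n = 3) as a bar; E+ day 110 libraries lie at 0.397 to 0.641 and control day 110 libraries at 0.344 to 0.510.

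At day 110, the question was which cotyledon genes differ between E+ and control ewes. A single gene passed the threshold. ENSOARG00000018366 was 13.9-fold lower in E+ ewes, at 1.55 ± 0.646 CPM against 22.7 ± 9.76 CPM in controls (SD, n = 3). Its log2 fold change was -3.80 with an SE of 0.481 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00878). All 3 E+ libraries lay below all 3 controls, with raw counts of 11, 10 and 3 against 61, 152 and 157. The gene lay at 8.64 CPM or above in each of the 12 libraries of the other groups. The deposited table does not pair its IDs with names, so its product is not stated here. No gene rose past the threshold.

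Of the 14653 genes tested at day 110, 850 had an unadjusted p under 0.05, where chance alone gives about 733. The groups did not overlap for 12.4% of genes, against 10% by chance. DESeq2 called 2 genes and limma-voom called 0. The call of ENSOARG00000018366 ended without control replicate 3 or any of the 3 E+ replicates, and when the fit used only the 6 libraries compared. Its log2 fold change stayed between -4.12 and -3.52 under all 20 alternatives, with adjusted p from 2.45e-11 to 0.67 (edgeR, DESeq2 or limma), and 12 of them kept the call.

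**Figure D2:**
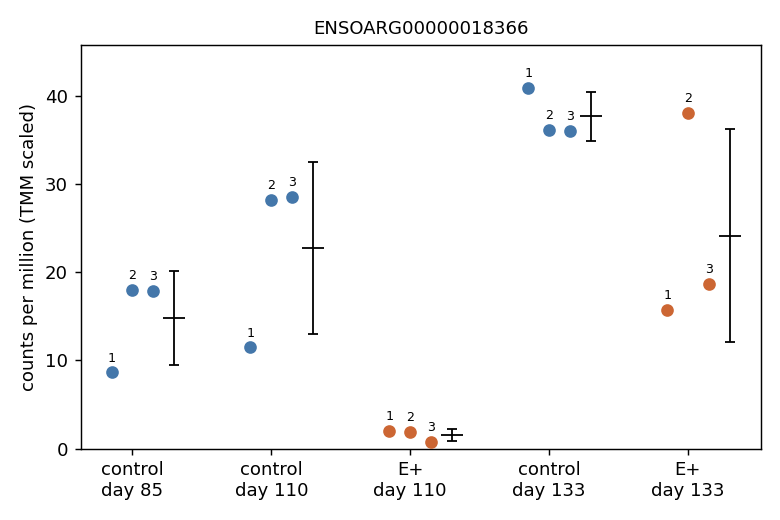
CPM (y axis, TMM scaled) of ENSOARG00000018366 in each library of the 5 groups (x axis), with replicate numbers beside the points and group means and SDs (n = 3) as bars. The 3 E+ day 110 libraries lie at 0.804 to 1.97 CPM, below the 8.64 CPM of the lowest library of any other group.

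At day 133, no gene differed between E+ and control cotyledons past the threshold. edgeR, DESeq2 and limma-voom each called 0 genes, and 316 genes had an unadjusted p under 0.05, fewer than the 733 that chance gives. The groups did not overlap for 4.59% of genes, against 10% by chance. ENSOARG00000018366 stood at 24.1 ± 12.1 CPM in E+ and 37.6 ± 2.80 CPM in control ewes (SD, n = 3), with a log2 fold change of -0.64 (SE 0.36, edgeR adjusted p = 1). Controls of this day were far apart on the first component, from -8.43 to 58.5.

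The effect of E+ feed was next compared between the days. No gene passed the threshold for a difference of the E+ effect (edgeR 0 genes, DESeq2 2, limma-voom 0), and 417 genes had an unadjusted p under 0.05. ENSOARG00000018366 had the smallest p of this test. Its E+ effect was higher at day 133 than at day 110 by 3.16 on the log2 scale (SE 0.607, edgeR unadjusted p = 8.33e-05, adjusted p = 1). The typical interval was wider here, 0.77 to either side. Averaged over both days, ENSOARG00000018366 was again the gene past the threshold, at a mean log2 fold change of -2.22 (SE 0.303, edgeR adjusted p = 0.0232). limma-voom called 0 genes for this mean, DESeq2 called 1, and 737 genes had an unadjusted p under 0.05. The call was lost on leaving out any 1 of the 12 libraries of those days except control day 110 replicate 1 and E+ day 133 replicate 2, while the log2 fold change in those fits was -2.31 to -2.09.

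Fold changes of E+ feed at the 2 days were weakly related across genes, with Pearson's r = 0.127 and Spearman's rho = 0.156. Of 100 splits of the libraries within days, the real one included, 60 gave an absolute r at least as large (permutation p = 0.6). Without control day 133 replicate 2 the r was -0.0576, without E+ day 133 replicate 1 it was -0.0671, and without control day 133 replicate 3 it was 0.384. With unadjusted p under 0.05 at both days there were 23 genes, where 18.3 would overlap if the days were independent, and 14 of the 23 had the same sign, where chance gives 50%. With 0 calls at day 133, an overlap of called genes could not be tested.

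In control ewes, 846 genes rose and 775 fell between days 85 and 133 (edgeR, Benjamini-Hochberg adjusted p under the threshold), 11.1% of those tested. The median change was 1.07 on the log2 scale among rises and -1.09 among falls, and 938 of the 1621 genes changed at least 2-fold. ENSOARG00000010046 rose from 0.189 ± 0.192 CPM at day 85 through 1.36 ± 0.777 at day 110 to 11.95 ± 2.42 at day 133 (SD, n = 3; edgeR adjusted p = 0.00141). The day 85 group held 3 counts of it and the day 133 group 184, a depth-scaled ratio of 65.3 with an exact 95% counting interval of 22 to 319.7. ENSOARG00000007498 fell from 15.8 ± 11.9 CPM through 1.24 ± 0.486 to 0.524 ± 0.588 (SD, n = 3; edgeR adjusted p = 0.00558). Its 253 counts at day 85 against 8 at day 133 gave a depth-scaled ratio of 29.7, with a counting interval of 14.8 to 69.5. Both intervals cover counting error only. With 2 or 3 surrogate variables, added after the data were seen, both calls ended. The log2 fold change of ENSOARG00000010046 was then 4.27 and 4.19 instead of 5.86 (adjusted p = 0.316 and 0.215, edgeR), and that of ENSOARG00000007498 was -2.57 and -4.28 instead of -4.86 (adjusted p = 0.747 and 0.341, edgeR). The latter call also ended with quality weights (adjusted p = 0.0566, limma). Over all 20 alternatives the adjusted p ran from 3.93e-07 to 0.316 for the rise and from 1.02e-05 to 0.747 for the fall. Without control day 85 replicate 1 or 2, or control day 133 replicate 1, the count of 1621 was 353, 355 and 388, and without control day 133 replicate 2 it was 2664.

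Between days 85 and 110, 16 genes rose and 6 fell in controls, with 800 at an unadjusted p under 0.05. All 22 changed at least 2-fold. Between days 110 and 133, 531 rose and 377 fell, and 515 of these 908 changed at least 2-fold. At day 110, control ewes had reached a median of 20.4% of the change from day 85 to day 133 of the rising genes and 22.2% of that of the falling genes. On the position measure, which leaves each library out in turn and weights genes by their change, they stood at 0.441 ± 0.0864, between 0.123 ± 0.104 at day 85 and 0.748 ± 0.161 at day 133 (SD, n = 3).

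The count between control days 110 and 133, where 3952 genes had an unadjusted p under 0.05, changed strongly when single libraries were left out. It was 0 without any of the 3 control day 110 libraries or control day 133 replicate 1, 4 without control day 133 replicate 3 and 2712 without control day 133 replicate 2. With only the 6 libraries compared it was 8, and with DESeq2 1877. Adding 2 surrogate variables, tried after the data were seen, gave 0 genes here and 1 gene from day 85 to day 133. Between days 85 and 110 the count was 9 to 17 with 1 library left out, 10 of them without the Type A library, control day 85 replicate 3, 10 without replicate 2, 9 without control day 110 replicate 2 or 3, and 54 with only those 6 libraries.

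In E+ ewes, 1 gene passed the threshold between days 110 and 133. ENSOARG00000018366 rose from 1.55 ± 0.646 to 24.1 ± 12.1 CPM (SD, n = 3), a log2 fold change of 3.89 (SE 0.481, edgeR adjusted p = 0.00642). In controls the same step was 0.73 for this gene (SE 0.361, edgeR adjusted p = 0.207). From day 85 to day 133 it rose past the threshold in controls, by 1.34 on the log2 scale (SE 0.369, edgeR adjusted p = 0.0326). No gene fell past the threshold in E+ ewes, whereas falls were most of the calls under 5 alternatives. At an unadjusted p under 0.05 there were 2199 genes in E+ and 3952 in control ewes. DESeq2 called 287 genes in E+ ewes, 234 of them falls, and limma-voom 0. The count was 0 without E+ day 110 replicate 1 or 2, 65 without E+ day 110 replicate 3, 54 of them falls, and 2 without E+ day 133 replicate 1. The log2 fold change of ENSOARG00000018366 in this step stayed between 3.34 and 4.12 under all 20 alternatives, and 15 kept the call.

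Most genes that changed in controls between days 110 and 133 had the same sign of change in E+ ewes, a comparison that shares no library. Of the 908, 885 (97.5%) had the same sign, against 75.5% of all tested genes. Rising genes had a median log2 fold change of 1.07 in controls and 0.49 in E+ ewes, and falling genes -0.997 and -0.69. Choosing genes by their control values enlarges the control side. The difference between the feeds had an unadjusted p under 0.05 for 146 of the 908 (16.1%), and none passed the threshold after adjustment (edgeR). Across all genes the fold changes of this step had r = 0.499 and rho = 0.624 between feeds, a relation computed after the data were seen. Without E+ day 110 replicate 2 this r was 0.308, and without control day 110 replicate 2 it was 0.328. Without E+ day 110 replicate 3, which lay among day 133 libraries on the first component, it was 0.608. Without that library and control day 133 replicate 2 it was 0.650. Then 933 genes passed the threshold in E+ ewes, against 65 without that library alone. Control day 133 replicate 2 is no part of that E+ step and acts on its count only through the filter, scaling and shared spread. Both were picked for lying away from their day on the first component, so leaving them out favours a higher r and more calls. How far E+ day 110 replicate 3 sets the smaller E+ medians was not tested. Of the 10 splits of the 6 E+ libraries, 2 gave an r as large as 0.499 (exact permutation p = 0.2, the smallest possible being 0.1).

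**Figure D3:**
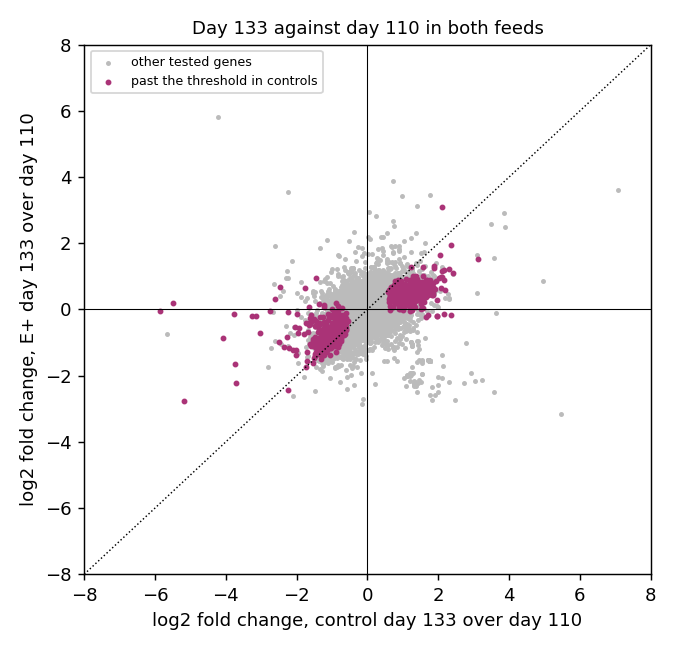
Log2 fold change of day 133 over day 110 in control ewes (x axis) and in E+ ewes (y axis), 1 point per tested gene, with the 908 genes past the threshold in controls in purple and equality as a dotted line. Of the purple points, 885 have the same sign on both axes, with medians of 1.07 and 0.49 among rises.

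The E+ effect was then set against the control time course. At day 110, genes that rose from day 85 to day 133 in controls had a median log2 fold change of 0.30 in E+ against control ewes, and genes that fell had -0.21. These sets passed camera with a preset correlation (p = 1.76e-15 and 9.62e-15), a test added after the data were seen, but not with an estimated correlation (p = 0.0917 and p = 0.0878), and not fry (p = 0.0742 and 0.0943). Across genes r was 0.405 and rho 0.413, and 2 of 10 splits of the 6 day 110 libraries gave as large an r (exact permutation p = 0.2, smallest 0.1). The relation rested on E+ day 110 replicate 3. Without that library r was 0.0349, and without control day 133 replicate 3 it was 0.153.

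Placed between control days 85 (0) and 133 (1), E+ day 110 libraries averaged 0.557 ± 0.139 and control day 110 libraries 0.441 ± 0.0864 (SD, n = 3; exact permutation p = 0.3, smallest 0.1). At day 133 the averages were 0.886 ± 0.156 in E+ and 0.748 ± 0.161 in control ewes (SD, n = 3; exact permutation p = 0.4). Part of that gap may come from the measure. In a single simulated run, libraries made at day 133 without any E+ effect averaged 0.841 as controls and 0.890 as E+. The run was not repeated, so the spread of that difference is unknown. At day 110, E+ ewes had covered a median of 47.7% of the change of the rising genes and 42.5% of that of the falling genes, or 36.7% and 32.8% without replicate 3. Single E+ libraries ranged from 24.8% to 72.0% for rises, and single controls from 11.4% to 32.5%. The control groups at both ends chose these genes, so day 133 controls stand at their own reference. The E+ effect at day 133 against the control change from day 85 to 110 had r = -0.0968 and rho = -0.0958, with 7 of 10 splits as large (exact permutation p = 0.7, smallest 0.1). Without control day 133 replicate 2 this r was 0.0313, and without control day 85 replicate 3 it was -0.0436.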

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

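Both tests of the counts in untested genes were chosen or changed only after the result was seen. Groups of 3 are too small for a test of single outlying libraries.

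The 12401 genes with counts too low for the tests held more counts in some E+ libraries than in any control. They took 5902 CPM in E+ day 133 replicate 1, 3555 in E+ day 110 replicate 3 and 3472 in E+ day 133 replicate 2. The 9 controls took 2016 to 3281, the highest being control day 133 replicate 3. The other E+ libraries lay within that range, at 2200 to 2848. Group means at day 133 were 3858 ± 1881 in E+ and 2564 ± 649.3 in control ewes (SD, n = 3, exact permutation p = 0.4). At day 110 they were 2890 ± 644.5 in E+ and 2457 ± 71.29 in control ewes (SD, n = 3, exact permutation p = 0.4). The smallest possible p was 0.1, a design too small to pass the threshold. With all libraries thinned to 4030388 counts, E+ day 133 replicate 1 still showed 22162 detected genes, above the 20229 of the highest control, which argues against sequencing depth. A few strongly expressed genes are argued against for that library too, since its surplus over the highest control made up 44.4% of these counts. The 1% most counted untested genes held 8.94% of them (counting SE 0.279) once the untested counts of each library were thinned to 10467, against 9.10% to 13.7% in controls with a median of 11.5%. That thinning of untested counts, and the comparison with the surplus, came after the shares at full depth had been seen (7.71% against 8.32% to 13.5% in controls). No other source of the surplus was tested. No biological explanation was tested, since the feed and the animals are confounded in single libraries.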

How the results depend on the processing

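The tests with quality weights, surrogate variables and both displaced libraries (E+ day 110 replicate 3 and control day 133 replicate 2) left out, and the correlation of the step from day 110 to 133 between feeds, were chosen only after the data were seen. Both displaced libraries were picked for their place on the first component, so leaving them out favours higher counts between days. The 3 other scalings and the filter of 1 CPM kept every count of genes within 1.5 times.

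E+ against control at day 110 gave 1 gene. It gave 6 without a filter, 2 with DESeq2, 4 with 1 surrogate variable and 3 with 3 of them. It gave 0 with limma-voom, with quality weights, with only the libraries compared and without the displaced libraries, and 0 to 1 leaving out 1 library. At day 133 the count was 0 under every alternative run. The difference between the days gave 0, but 1 without a filter, 2 with DESeq2 and 4 with 1 surrogate variable, and 0 leaving out any 1 library. The mean E+ effect gave 1, but 0 with limma-voom, with quality weights and without the displaced libraries, 3 with 3 surrogate variables, and 0 to 1 leaving out 1 library.

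Control day 110 against day 85 gave 22 genes. It gave 64 without a filter, 71 with DESeq2, 54 with only the libraries compared, 103 with quality weights, 44, 47 and 38 with 1, 2 and 3 surrogate variables, 40 without the displaced libraries and 9 to 17 leaving out 1 library. Control day 133 against day 110 gave 908. It gave 1877 with DESeq2, 8 with only the libraries compared, 3515 with quality weights, 215 with 1 surrogate variable, 0 with 2 or 3, 3151 without the displaced libraries and 0 to 2712 leaving out 1 library. Control day 133 against day 85 gave 1621. It gave 650 with only the libraries compared, 3472 with quality weights, 1029, 1 and 10 with 1, 2 and 3 surrogate variables, 3121 without the displaced libraries and 353 to 2664 leaving out 1 library. E+ day 133 against day 110 gave 1. It gave 119 without a filter, 287 with DESeq2, 929 with quality weights and 933 without the displaced libraries, of which 98, 234, 660 and 674 were falls, against a single rise as reported. It gave 0 with limma-voom and with 2 or 3 surrogate variables, and 0 to 65 leaving out 1 library. The cause of these moves was not tested.

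Leaving out 1 library, the r between the E+ effects of both days ran from -0.0671 to 0.384, reversing at -0.0576 without control day 133 replicate 2 and at -0.0671 without E+ day 133 replicate 1. The r of the E+ effect at day 110 with the time course ran from 0.0349 to 0.490, and was 0.0296 without the displaced libraries. The r of the E+ effect at day 133 with the early time course ran from -0.130 to 0.0313, reversing at 0.0313 without control day 133 replicate 2 and at 0.0252 without the displaced libraries. Between feeds, the r of the step from day 110 to 133 ran from 0.308 to 0.608, and was 0.650 without the displaced libraries and 0.656 on mean differences of log2 CPM. The cause was not tested.

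Equal replicate numbers did not pair the animals. Of 30 pairs of the same number, 12 correlated above 0.1 (range -0.338 to 0.444), and 6 of 15 libraries were closest to their own number. With a replicate block, control day 133 against day 110 gave 1376 genes, and the r of the E+ effect at day 133 with the early time course was 0.106. The block changed no other count by over 1.5 times.

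The gene list tests were not run, for lack of gene symbols. Totals of 4030388 to 6159405 counts and 3 animals per group left typical intervals of 0.54 on the log2 scale.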

Other observations

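The tests of an exchange of labels, including the single gene used there, the scaling and animal tests of the single E+ gene, and the counts with displaced libraries left out were chosen only after the results were seen. The counts over other splits of the libraries and the depth and abundant-gene tests of the displaced library were set before.

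Among the genes of the control time course, E+ ewes at day 133 stood close to day 133 controls. They had covered a median of 91.4% of the change of the 846 rising genes and 94.96% of that of the 775 falling genes. Single E+ day 133 libraries ranged from 76.3% to 100.6% for rises and from 79.6% to 104.9% for falls, lowest in replicate 1 for both. Control libraries of day 133 define 100% here and give no independent range.

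E+ day 110 replicate 3 lay beside the day 133 libraries on the first component, at 48.0 against -39.3 to -16.0 for the other 5 day 110 libraries, although its position between control days 85 and 133 was 0.634, within their 0.344 to 0.641. Its median share of the control change, 72.0% for rises and 61.4% for falls, was above theirs of 11.4% to 50.1% and 13.9% to 45.2%. Lower depth and a few very abundant genes are argued against, since its score was 44.8 with all libraries thinned to the same total and 47.9 without the 20 most abundant genes. An exchange of labels is not settled, as the lowest position was 0.708 among E+ day 133 and 0.571 among control day 133 libraries, neither further above 0.641 than the SD of 0.114 among those 5. ENSOARG00000018366 ranked 1 by p at day 110 also without this library, though not past the threshold (edgeR adjusted p = 0.101). It lay at 0.804 CPM in this library, 1.97 and 1.87 in the other E+ day 110 libraries and 15.7 to 40.9 in day 133 libraries. That speaks against an exchange only if its low value marks the group, and an animal difference stays open. Genes, this one included, that set those other E+ day 110 libraries at least 2-fold apart were sought with each possible partner left out. Control day 133 replicate 2 was placed with them by 1 of 3 genes, and E+ day 133 replicate 3 by 1 of 2. E+ day 110 replicate 3 was placed with them by 1 gene in both cases. For each other day 133 library the only gene was ENSOARG00000018366, which kept the labels. Leaving a partner out admits genes in which it lies near those libraries, so the added genes cannot decide on an exchange. An early course of the cotyledon in E+ day 110 replicate 3 stays open as untested.

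ENSOARG00000018366 was low in the 3 E+ day 110 libraries. TMM factors ran from 0.842 to 1.07 and shift all genes of a library together, far short of its 13.9-fold difference. With 3 other scalings its log2 fold change moved at most to -3.80, against an SE of 0.481. That outcome was nearly fixed in advance by the narrow range of the factors. A difference between animals unrelated to the feed stays open. Of 12265 genes, 8 had their 3 lowest of the 12 libraries of days 110 and 133 at least 2-fold below the next, and 1 had them in a single group, where 0.146 would by chance (exact binomial p = 0.137). That setting was the last of 3 tried, and the p moved with it. A 4-fold gap over all 15 libraries gave an exact binomial p = 0.000121 from 2 genes. Any of those 2 other than ENSOARG00000018366 had its low libraries in control day 85, so it says nothing about the feed. A 3-fold gap over the 12 libraries gave an exact binomial p = 0.0182 from 1 gene, ENSOARG00000018366. No p of the 3 stands as a planned test. Among the 8 genes, the gap of ENSOARG00000018366 was 5.05-fold, and those of the others were 2.01-fold to 2.43-fold. An animal difference would be shown by as large a gap with low libraries in different groups, and none of these 8 genes had one. In the other direction, 60 genes had their 3 highest libraries at least 2-fold above the next, and 0 of them in a single group. Gaps across groups thus occurred, so the lack of a large low one does not argue against an animal difference.

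Other splits of the libraries were counted for each comparison. Splits of 6 libraries number 10, too few for a share under 0.05. In E+ against control at day 110 the real split gave 1 gene and the others at most 0, and at day 133 the real split gave 0, which all 10 reach by construction, and the others at most 2. In controls, the real splits gave 22 genes between days 85 and 110, 908 between days 110 and 133 and 1621 between days 85 and 133, and in E+ ewes 1 gene between days 110 and 133. The highest other split gave 0 in each of these 4 comparisons.

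The real difference of the E+ effect gave 0 genes, which all 100 splits within days reach by construction, so that count says nothing about chance. Of the other splits, 1 gave 64 genes and 1 gave 39, for a reason that was not tested. For the mean E+ effect, 5 of 100 splits gave at least the 1 gene of the real one, with a highest other of 2, and chance is not excluded.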
